A study of Mus musculus with 9 samples.

How the data were processed

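RNA was measured in 9 fetal mouse brains of strain C57 Bl/6J at embryonic day 14.5, with 3 libraries from each of 3 maternal microbiome groups. These were specific pathogen free (SPF, the control), antibiotic-treated (ABX, the perturbation) and colonised with spore-forming bacteria (SP, the restoration). Total RNA was made into Illumina libraries, per the labels' protocols. FastQC and HISAT2 2.1.0 were used with genome build mm10, per the submitters' processing notes. The program that counted reads, its strand setting and the gene annotation are not given in the sources used here. The deposited values are whole counts of reads per gene symbol for each library, with no normalization. Because strand use is unknown, overlapping and antisense genes cannot be told apart, and genes with near-identical copies (histones, ribosomal proteins with pseudogenes) are uncertain. Gapdh had 43 to 407 counts and Ppia 24 to 1491, and neither was used as a reference.

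Each library listed 24421 gene symbols and 5 closing entries that name no gene and have the form htseq-count writes. Those 5 stayed out of library sizes and tests. Of the listed reads, 28.0% to 31.1% were in genes, 47.4% to 59.3% in no feature, 0.312% to 0.429% in more than 1 gene and 11.6% to 24.2% aligned to more than 1 place. Gene counts came to 6540130 to 9229112 per library (median 8030556). No replicate pair was a duplicate: the chi-square statistic per degree of freedom between replicates ran from 7.65 to 57.9. Coordinates are for GRCm38, the assembly of mm10, from GENCODE, matched by symbol for 13954 of 14528 tested genes.

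The main test was edgeR 4.0.16 (robust quasi-likelihood F test) in R 4.3.3 with TMM scaling. The 9 libraries entered 1 fit with group as the only factor. Genes passing filterByExpr numbered 14528, and 9893 did not enter. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The 4 contrasts were ABX against SPF, SP against ABX, SP against SPF, and ABX against the mean of SPF and SP. The common dispersion was 0.0281, a biological coefficient of variation of 16.8%. A value given for a gene without a unit is its log2 fold change, with the standard error (SE) after ±, and levels as CPM, counts scaled to the TMM-normalised library size, with the standard deviation (SD). The labels do not say that the fetuses came from separate dams or litters, so p-values measure only the spread between these samples. Each group held both sexes, so part of that spread lies between fetuses, and part may be technical.

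Gene lists were fixed before the data were examined, 31 in all. They cover axon guidance, thalamic identity, neural cell types and brain positions, cells from outside the neural lineage, and stress, metabolic, ribosomal, histone, interferon, microbial metabolite and sex-linked genes. The list of mitochondrially encoded genes had 0 members in the files, which left 30. Each was tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. The symbols Scn2a, Ahsp, Epb42 and Cnmd were not found.

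Genes named in the text follow a rule written before the data were examined. It takes genes past the threshold with groups that do not overlap, otherwise the 10 smallest p-values of a contrast, the 3 members of each list with the smallest p, Ntng1 and the sex-linked genes. From these, the members of lists past the threshold and a few others are described. Separation of the groups was tested exactly over the 280 groupings of 9 libraries into 3 groups of 3, on log2 CPM (prior count 2) of the 500 most variable genes. Reversal was set beside 100 simulated data sets with no effect, since both contrasts share the ABX libraries.

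The procedure was tested on simulated counts for ABX against SPF over 14528 genes. It recovered 30.8% of genes changed 1.5-fold (206 of 670), 67.3% of those changed 2-fold (451 of 670) and 87.9% of those changed 4-fold (580 of 660). Of its calls, 7.34% were false. In all simulations here genes varied independently, without the differences between libraries that real genes share. Recovery in the real data may therefore be lower. Alternatives were DESeq2 1.42.0, limma-voom, other size factors, other filters, fits of the compared groups alone, a covariate for Y-linked genes, removal of red blood cell genes, a replicate block and leaving out each library. Covariates for head tissue genes and Rn45s, and removal of Rn45s and Lars2, were chosen after seeing the data. Rn45s was higher in each ABX library than in the other 6, so as a covariate it is confounded with the group in contrasts with ABX. A reversal under it may come from taking out a group difference.

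Replicate numbers might pair samples, so deviations from group means were correlated between same-numbered libraries. For SPF and SP the 3 correlations were 0.202, 0.228 and 0.166. For SPF and ABX they were -0.300, 0.174 and 0.144, and for ABX and SP -0.333, 0.0279 and -0.0175. Every pair was above 0.1 for SP against SPF alone, where differently numbered libraries ran from -0.167 to -0.0380. Deviations from a group mean cancel out over its 3 libraries, so positive same-numbered values push the others negative on average. The negative values are therefore no separate evidence of pairing. In the other comparisons differently numbered libraries reached 0.297 (SPF replicate 1 and ABX replicate 3) and 0.273 (ABX replicate 3 and SP replicate 1). Both lie above every same-numbered value, so the correlations do not show that the replicate numbers pair samples. The numbers were taken from the sample titles. The labels do not say what they mark, and the names of the deposited count tables carry other numbers for most libraries, so the pairing and the replicate block rest on the titles alone.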

Results

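The study asked how the maternal microbiome relates to gene expression in the fetal brain. Total RNA was sequenced from 3 SPF, 3 ABX and 3 SP brains at embryonic day 14.5. Libraries held 6540130 to 9229112 gene counts and 17523 to 17990 detected genes. Libraries of 1 group were no closer to each other than to those of other groups. The ratio of between-group to within-group variation was 0.176, and 271 of the 280 groupings gave a ratio as large (exact permutation p = 0.968). It was 0.303 without SPF replicate 2 (192 of 280, p = 0.686), 0.290 without ABX replicate 3 (214 of 280, p = 0.764) and 0.265 without SP replicate 1 (220 of 280, p = 0.786), by the same exact permutation. The correlation of log2 CPM had a median of 0.969 within groups and 0.974 between groups. Y-linked genes were expressed in 2 SPF, 2 ABX and 1 SP libraries, and Xist in 1 SPF, 1 ABX and 2 SP libraries. Genes of cartilage and muscle differed strongly between libraries within every group. The mean log2 deviation of that list ran from -1.32 to 1.15 in SPF, from -1.44 to 2.16 in ABX and from -1.31 to 1.35 in SP.

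Ntng1 encodes netrin-G1, a membrane protein of thalamocortical axons, and lies on chromosome 3 (109780040 to 110144011, minus strand, mm10; ENSMUSG00000059857). Its level was 49.3 ± 2.65 CPM in SPF, 46.5 ± 8.19 in ABX and 43.1 ± 6.55 in SP (mean ± SD, n = 3 each). The log2 fold change was -0.09 ± 0.14 (SE) in ABX against SPF, with a 95% interval from -0.39 to 0.22. In SP against ABX it was -0.10 ± 0.14, from -0.41 to 0.20, and in SP against SPF -0.19 ± 0.14, from -0.50 to 0.11. Unadjusted p-values were 0.547, 0.483 and 0.199. None of the 3 intervals excluded 0. The first value was 0.01 without ABX replicate 3. The second was 0.04 without ABX replicate 1, 0.01 without SP replicate 3 and 0.23 with Rn45s as a covariate.

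**Figure D1:**
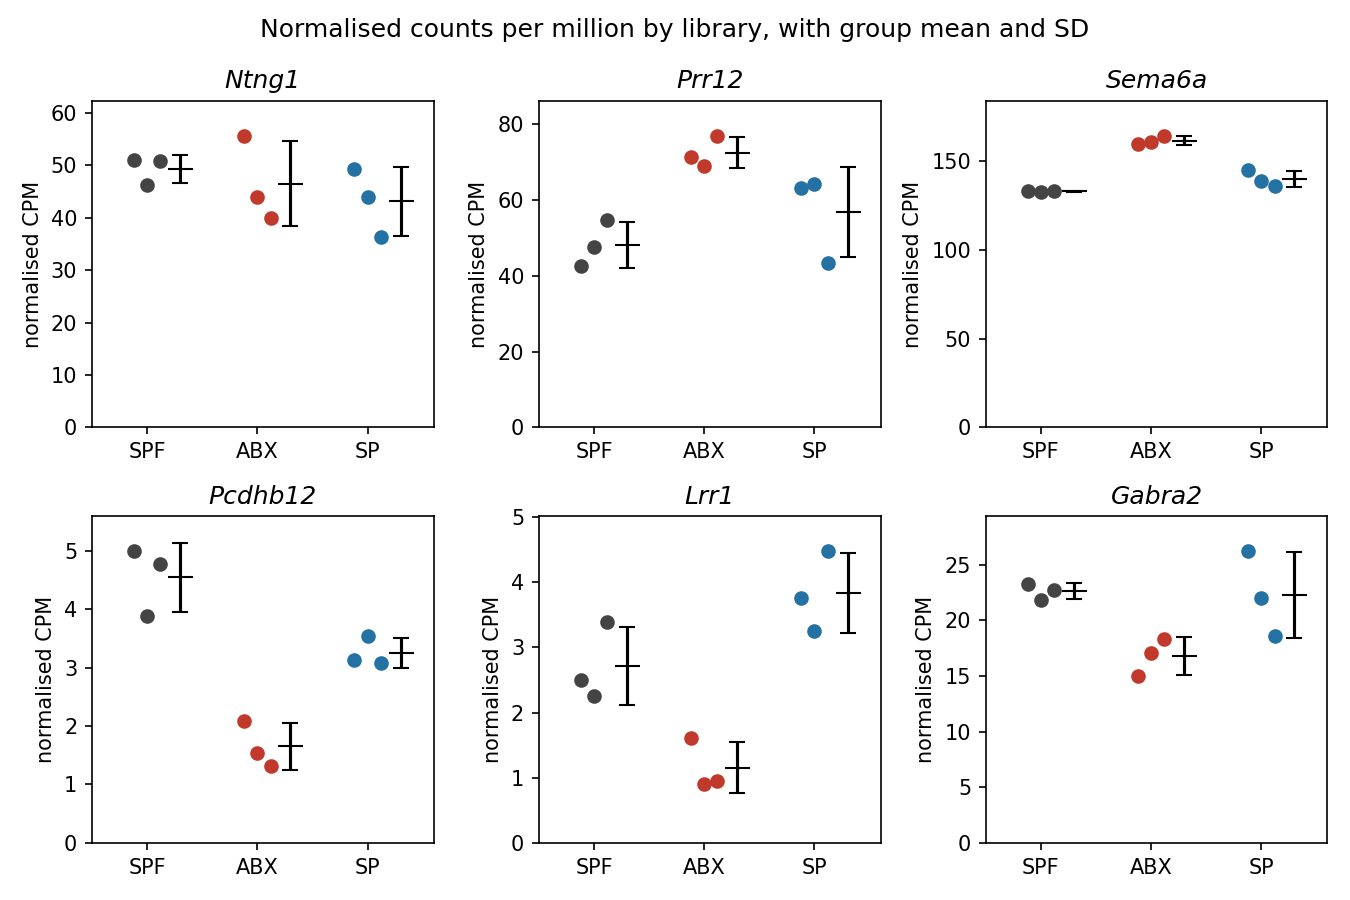
Normalised CPM (y axis) of Ntng1, Prr12, Sema6a, Pcdhb12, Lrr1 and Gabra2 in each library of the SPF, ABX and SP groups (x axis), with points for libraries and bars for the mean ± SD. Sema6a lies at 133 ± 0.468 in SPF and 161 ± 2.62 in ABX, while Ntng1 overlaps between all groups, and none of these genes passed the adjusted threshold.

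ABX against SPF asks what depletion of the maternal microbiome does to the fetal brain. The gene with the smallest p was Prr12, which encodes a proline-rich nuclear protein (chromosome 7, 45027563 to 45052881). It stood at 48.2 ± 6.08 CPM in SPF and 72.4 ± 4.09 in ABX, a log2 fold change of 0.59 ± 0.14. Sema6a, a semaphorin that guides axons (chromosome 18, 47235598 to 47368870), had 0.28 ± 0.08. Pcdhb12, a clustered protocadherin (chromosome 18, 37435621 to 37438654), had -1.47 ± 0.38, with 4.55 ± 0.589 CPM in SPF and 1.65 ± 0.398 in ABX. The synaptic vesicle gene Sv2b had -0.58 ± 0.16, and the atrophin gene Atn1 0.49 ± 0.13. Polr3c, a subunit of RNA polymerase III, had 0.52, the DNA damage gene Mdc1 0.40, Smpdl3a -0.78, the low-count gene Creb3l1 2.17 and 6330549D23Rik 0.68. Each of these 10 had groups that did not overlap, and none passed the adjusted threshold. Groups did not overlap for 1225 genes in all (8.43%), where chance gives 10%.

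The edgeR test called 0 of 14528 genes, with 356 at an unadjusted p under 0.05 (189 higher and 167 lower in ABX). The count of 356 became 815 without SPF replicate 3, 556 without SP replicate 3, 551 with Y-linked and head tissue covariates and 696 with Y-linked and Rn45s covariates. DESeq2 called 0, with 350 at an unadjusted p under 0.05, and limma-voom called 0, with 390. DESeq2 ran without the edgeR filter and tested 20172 genes in each contrast, so its counts are out of a larger total. The 95% interval lay within a 2-fold change for 80.4% of genes. Each interval is for 1 gene, with no adjustment over the genes tested, so larger differences are not excluded for all of those genes together. The spread is that between these samples, and the labels do not say that they came from separate dams.

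Among the fixed lists, 7 of 30 passed the camera threshold in ABX against SPF. Replication-dependent histones were higher, with 51 of 57 members positive and a median log2 fold change of 0.19 (adjusted p = 8.44e-09, but adjusted p = 0.832 with an estimated correlation). Hist1h2bg had 0.29 ± 0.11, Hist1h4b 0.33 ± 0.14 and Hist2h3b 0.41 ± 0.18. Cell cycle genes were also higher (35 of 40 positive, adjusted p = 0.0229, but adjusted p = 0.832 with an estimated correlation), with 0.61 ± 0.24 for the cyclin gene Ccne1. Genes of intermediate progenitors and neurogenesis were higher in 15 of 18 cases (adjusted p = 0.0390, but adjusted p = 0.832 with an estimated correlation), with Tox3 at 0.26, the proneural gene Neurog1 at 0.86 and Chd7, a chromatin remodeller, at 0.16. For midbrain, hindbrain and spinal cord position, 11 of 17 were positive (adjusted p = 0.0148, but adjusted p = 0.832 with an estimated correlation), with 0.57 for En2, 0.81 for Fgf17 and 0.27 for Lhx1. Genes of cartilage, muscle and skin of the head were positive in 18 of 21 cases (adjusted p = 0.0390, but adjusted p = 0.832 with an estimated correlation), with the muscle genes Mylpf at 2.70 ± 1.14 and Actc1 at 3.34 ± 2.14. Both values rest on ABX replicate 1 (8.53 CPM for Mylpf and 13.4 for Actc1), and without it they were 0.70 and -2.47. With Rn45s as a covariate they were -1.26 and -3.23. Oxidative phosphorylation genes were lower (39 of 47 negative, adjusted p = 0.00500, but adjusted p = 0.832 with an estimated correlation), with Ndufs4 of complex I at -0.25 (0.00960 with Y-linked genes and Rn45s as covariates) and the ATP synthase genes Atp5h and Atp5o at -0.18 and -0.16. Ribosomal protein genes were lower in 53 of 75 cases (adjusted p = 0.0390, but adjusted p = 0.832 with an estimated correlation), with Rpl10 at -0.14 and Rpl31 at -0.16. The same ABX libraries held 5.07% to 14.9% of gene counts in Rn45s, against 0.888% to 3.05% in SPF, and 15.9% to 24.2% of reads aligned to more than 1 place, against 11.6% to 14.5%.

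Across the lists fry called 0. No list had a member past the threshold, and the count adjusted over the list alone was 0 in each. Histones were the only one of the 7 that passed without each of the 9 libraries in turn, with a highest adjusted p of 0.00733 (without SPF replicate 1). These fits kept camera's preset correlation of 0.01, while the estimated correlation was 0.733 for histones and 0.737 for cell cycle genes. Leaving out libraries therefore does not show that the histone call holds beyond the preset correlation. The count of lists was 3 without SPF replicate 1. The head tissue list turned negative without ABX replicate 1 (adjusted p = 0.124), and cell cycle genes without SPF replicate 2 (adjusted p = 0.775). Other calls ended, with the adjusted p in parentheses, without SPF replicate 1 (head tissue 0.345, progenitors 0.110, hindbrain 0.110, ribosomal 0.0502), SPF replicate 2 (progenitors 0.954, oxidative phosphorylation 0.130, ribosomal 0.278) and SPF replicate 3 (head tissue 0.289, hindbrain 0.473, ribosomal 0.0538). The same held without ABX replicate 2 (ribosomal 0.201) and ABX replicate 3 (cell cycle 0.761, progenitors 0.798, ribosomal 0.0869).

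The other lists did not pass in ABX against SPF. Axon guidance genes had 69 of 110 positive (adjusted p = 0.193), with 0.37 ± 0.15 for Celsr2 and 0.24 ± 0.10 for the receptor gene Ephb2. Thalamic identity genes had 15 of 24 positive (adjusted p = 0.374), with 0.71 ± 0.33 for Irs4, which reversed to -0.25 with Rn45s as a covariate and to -0.52 with Y-linked genes and Rn45s. Synapse genes had 26 of 45 negative (adjusted p = 0.277), with -0.43 ± 0.16 for the GABA receptor gene Gabra2, -0.52 for the NMDA receptor gene Grin1 and -0.32 for the AMPA receptor gene Gria1. Adjusted p was 0.0676 for pituitary and hypothalamus, 0.177 for endothelium and for choroid plexus, 0.184 for telencephalon position and 0.374 for microglia. It was 0.397 for red blood cells, 0.453 for radial glia, 0.479 for excitatory cortical neurons, 0.663 for oligodendrocyte precursors, 0.951 for pericytes and meninges and 0.966 for GABAergic neurons. It was 0.277 for the integrated stress response and for one-carbon and carnitine metabolism, 0.712 for interferon, hypoxia and monoamine neurons, 0.912 for immediate early and cholesterol genes and 0.966 for microbial metabolite sensing and sex-linked genes. Median, mean and test differed in sign for monoamine neurons, immediate early, hypoxia, microbial metabolite and sex-linked genes.

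**Figure D2:**
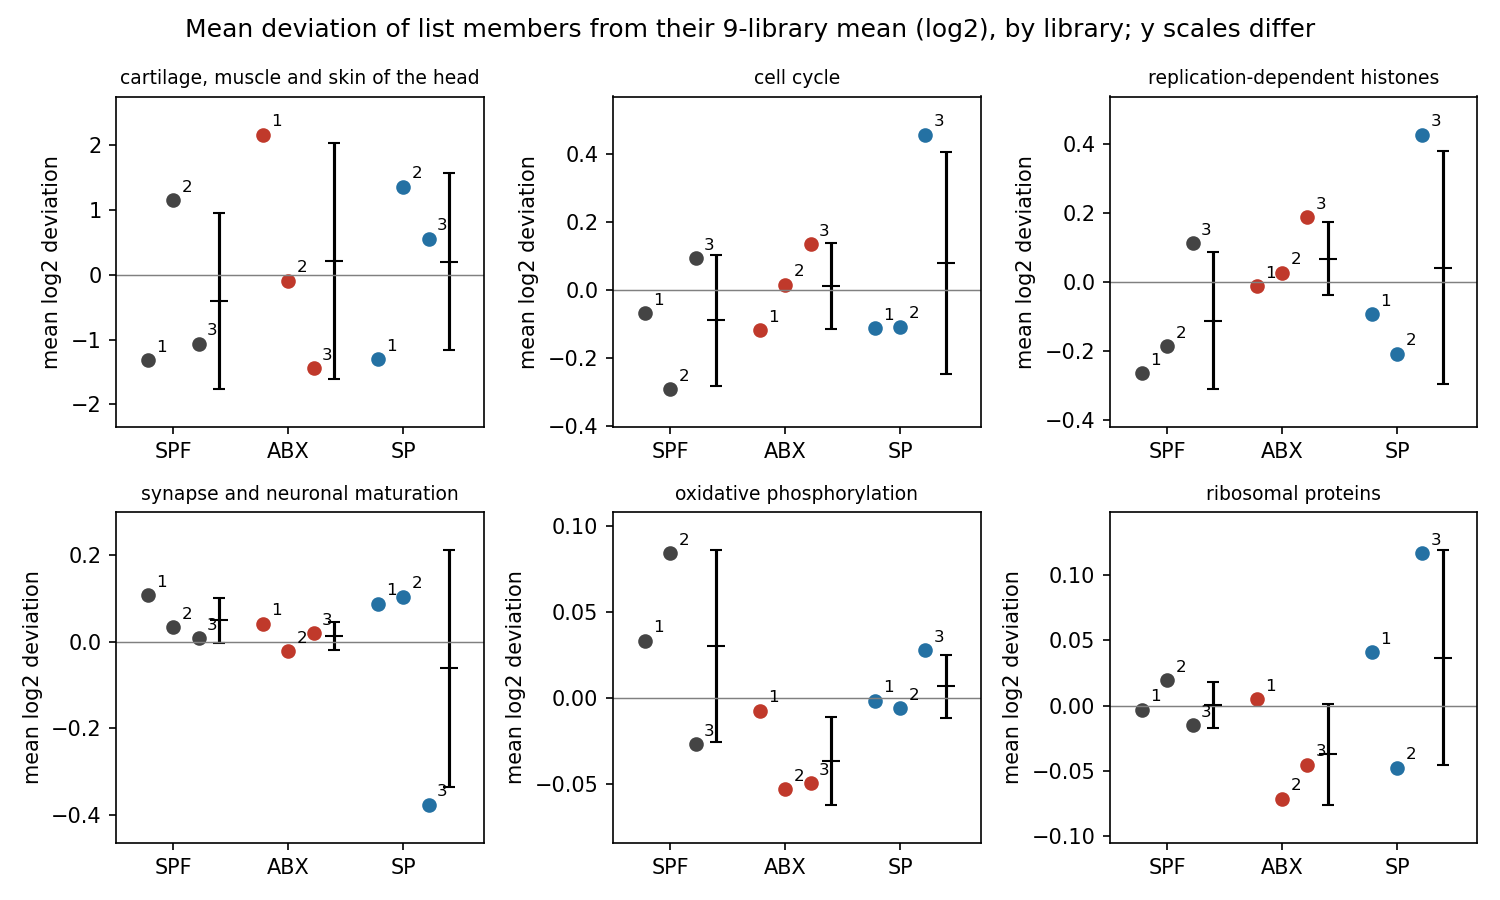
Mean log2 deviation of the members of 6 lists from their mean over the 9 libraries (y axis, with a different scale in each panel) for each library of SPF, ABX and SP (x axis), with replicate numbers beside the points and bars for the mean ± SD. SP replicate 3 stands at 0.46 for cell cycle and -0.38 for synapse genes, while SP replicates 1 and 2 lie at -0.11 and -0.11 for cell cycle and at 0.09 and 0.10 for synapse genes.

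SP against ABX asks whether colonisation with spore-forming bacteria changes expression relative to the depleted state. Lrr1, a subunit of a ubiquitin ligase that acts in DNA replication (chromosome 12, 69168814 to 69179009), was at 1.16 ± 0.393 CPM in ABX and 3.83 ± 0.616 in SP, a log2 fold change of 1.74 ± 0.44. The kinase gene Sgk3 had 0.91 ± 0.24. Lower values in SP were those of Ube2j2, a ubiquitin-conjugating enzyme (-0.82 ± 0.24), the xylosyltransferase gene Xylt1 (-0.53 ± 0.16) and the sodium-calcium exchanger gene Slc24a3 (-0.67 ± 0.20). The other 5 of the 10 smallest p-values belonged to AW209491 (-0.60), Ddx27 (0.37), Map3k19 (-1.86), Thoc7 (0.40) and 3830406C13Rik (-0.61). From other lists, Sema6a had -0.21 ± 0.08, Gabra2 0.41 ± 0.16, Cplx2 -0.26, Irs4 -0.94, the glycolytic gene Aldoc -0.38, Cycs, which encodes cytochrome c, 0.47, Atp5h 0.22, Dlx5 -0.97 and Mvk -0.33. With Y-linked genes and Rn45s as covariates Irs4 reversed to 0.33, Cycs to -0.0199 and Thoc7 to -0.00291, and with Rn45s alone Dlx5 reversed to 0.0664. None passed. The edgeR test called 0 of 14528 genes, with 294 at an unadjusted p under 0.05 (142 higher, 152 lower; 443 without SP replicate 1, 499 with Y-linked and Rn45s covariates), and DESeq2 and limma-voom called 0, with 285 and 283. Groups did not overlap for 1203 genes (8.28%, chance 10%).

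In this contrast camera called 2 of 30 lists. Ribosomal protein genes were higher in SP in 60 of 75 cases (adjusted p = 0.000193, but adjusted p = 0.969 with an estimated correlation), with Rpl19 at 0.33, Rpl3 at 0.23 and Rps12 at 0.21. Rn45s held 1.54% to 2.68% of gene counts in SP and 5.07% to 14.9% in ABX, and reads aligned to more than 1 place were 13.2% to 13.8% and 15.9% to 24.2%. Cell cycle genes were higher in 34 of 40 cases (adjusted p = 0.0433, but adjusted p = 0.969 with an estimated correlation), with the mitotic genes Ccnb2 at 0.27, Aurka at 0.31 and Ccnb1 at 0.22. All 3 reversed with Y-linked genes and Rn45s as covariates (-0.0679, -0.20 and -0.48), and Aurka and Ccnb1 also with Rn45s alone (-0.0476 and -0.11). The count adjusted over the list alone was 0 in both. Without SP replicate 3 the cell cycle list turned lower in SP and passed in that direction (adjusted p = 6.72e-05), and ribosomal protein genes had an adjusted p of 0.355. The cell cycle call also ended without SPF replicate 1 (adjusted p = 0.0643), ABX replicate 1 (0.632) and ABX replicate 2 (0.0850). The count of lists was 1 without SPF replicate 1, 4 without ABX replicate 1, 5 without SP replicate 1 and 6 without SP replicate 2 or SP replicate 3. Median, mean and test differed in sign for excitatory neurons, immediate early, integrated stress, microbial metabolite and histone genes, none of them called.

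SP against SPF asks whether the spore-former group differs from the control. 2810049E08Rik had the smallest p, with 3.51 ± 0.979 CPM in SPF and 0.900 ± 0.139 in SP (-1.94 ± 0.47). Prrg1 had 0.82 ± 0.24, Proca1 1.66 ± 0.50, the steroid dehydrogenase gene Hsd3b6 1.22 ± 0.38 and Taf1a, of the RNA polymerase I machinery, -0.46 ± 0.14. The remainder of the 10 were AW209491 (-0.60), 1810055G02Rik (0.67), 3830406C13Rik (-0.62), Zmym1 (0.36) and Mum1 (0.36), and Efna3 of the axon guidance list had -0.69 ± 0.25. None passed. The edgeR test called 0 of 14528 genes, with 280 at an unadjusted p under 0.05 (130 higher, 150 lower). That count was 505 without SPF replicate 3 and 456 without SP replicate 1. With no filter beyond a total of 1 count it was 422, out of 20182 genes. DESeq2 and limma-voom called 0, with 267 and 307 at an unadjusted p under 0.05. Groups did not overlap for 923 genes (6.35%, chance 10%).

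Here camera called 7 of 30 lists. Cell cycle genes were higher in SP in 38 of 40 cases (adjusted p = 3.38e-08, but adjusted p = 0.856 with an estimated correlation), with the ribonucleotide reductase gene Rrm2 at 0.36, Ccne1 at 0.52 and Mcm4 at 0.25. Histones were higher in 53 of 57 cases (adjusted p = 4.03e-08, but adjusted p = 0.856 with an estimated correlation), with Hist1h2bg at 0.27 and Hist2h2ac at 0.34. Synapse genes were lower in 35 of 45 cases (adjusted p = 0.000643, but adjusted p = 0.856 with an estimated correlation), with the neuronal splicing factor gene Rbfox3 at -0.31, Grin1 at -0.46 and Syt1 at -0.21. Endothelial genes were higher in 17 of 24 cases (adjusted p = 0.0134, but adjusted p = 0.755 with an estimated correlation), with Eng at 0.57 and Ly6e at 0.37 but Sox17 at -0.74. Red blood cell genes were higher in 11 of 13 cases (adjusted p = 0.00640, but adjusted p = 0.755 with an estimated correlation), with Slc4a1 at 0.74 and the embryonic globin gene Hba-x at 0.81. Midbrain, hindbrain and spinal cord genes were called higher (adjusted p = 0.0160, but adjusted p = 0.755 with an estimated correlation) with a median of 0.04 and a mean of -0.01, which differ in sign, and with Fgf17 at 1.02, En2 at 0.58 and En1 at 0.47. Choroid plexus genes were lower in 11 of 17 cases (adjusted p = 0.0134, but adjusted p = 0.856 with an estimated correlation), with Htr2c at -0.95, Clic6 at -0.51 and Kcne2 at -0.56. The count adjusted over the list alone was 0 in each list. Without SP replicate 3 the cell cycle and histone lists were negative (adjusted p = 0.400 and 0.126) and the synapse list positive (adjusted p = 0.184). The count of lists was then 2, and it was 1 without SPF replicate 1 and 11 without SP replicate 1. Without SPF replicate 1 adjusted p was 0.199 for synapse, 0.214 for choroid plexus, 0.238 for endothelial, 0.0601 for red blood cell, 0.354 for hindbrain and 0.05004 for histone genes. Calls also ended, with the adjusted p in parentheses, without SPF replicate 2 (cell cycle 0.1003, choroid plexus 0.203, red blood cells 0.220), SPF replicate 3 (hindbrain 0.733), SP replicate 2 (choroid plexus 0.227, endothelium 0.205, red blood cells 0.204) and SP replicate 3 (choroid plexus 0.260, hindbrain 0.211). Median, mean and test also differed in sign for radial glia, oligodendrocyte precursors, pituitary and microbial metabolite genes, none of them called.

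ABX against SPF and SP together asks what sets the depleted group apart from both groups with a microbiome. Ube2j2 was at 11.7 ± 1.66 CPM in ABX, 7.08 ± 1.29 in SPF and 6.63 ± 0.369 in SP, a log2 fold change of 0.77 ± 0.20. Prr12 had 0.47 ± 0.12, Atn1 0.42 ± 0.12 and Sema6a 0.24 ± 0.07. Lower in ABX were Sgk3 (-0.80 ± 0.21), Lrr1 (-1.49 ± 0.40), Pcdhb12 (-1.23 ± 0.35) and the taste receptor gene Tas1r1 (-1.28 ± 0.36), and 6330549D23Rik had 0.57 ± 0.17. Rn45s, the ribosomal RNA precursor, had 2.41 ± 0.51, with 14.9%, 8.95% and 5.07% of gene counts in the 3 ABX libraries and 0.888% to 3.05% in the other 6. The synaptic gene Gabra2 had -0.42 ± 0.14, and Irs4 0.83 ± 0.28, which reversed to -0.10 with Rn45s as a covariate and to -0.43 with Y-linked genes and Rn45s. The edgeR test called 0 of 14528 genes, with 334 at an unadjusted p under 0.05 (186 higher, 148 lower). That count was 566 without SPF replicate 3, 543 without SP replicate 3 and 619 with Y-linked and Rn45s covariates. With no filter beyond a total of 1 count it was 528, out of 20182 genes. At an unadjusted p under 0.05, limma-voom had 323 and DESeq2 313. Of these, limma-voom called 0 and DESeq2 called 1, Rn45s (adjusted p = 0.0255). Groups did not overlap for 288 genes (1.98%, chance 2.38%).

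Of the 30 lists, camera called 3 in this contrast. Ribosomal protein genes were lower in ABX in 62 of 75 cases (adjusted p = 0.000828, but adjusted p = 0.994 with an estimated correlation), with Rpl3 at -0.20 and Rpl31 at -0.18. Oxidative phosphorylation genes were lower in 38 of 47 cases (adjusted p = 0.00629, but adjusted p = 0.994 with an estimated correlation), with Atp5h at -0.20 and Cycs at -0.34. Cycs reversed to 0.10 with Rn45s as a covariate and to 0.16 with Y-linked genes and Rn45s. Reads aligned to more than 1 place were 15.9% to 24.2% in ABX and 11.6% to 14.5% in the other 6 libraries, beside the Rn45s shares above. Histones were higher in 48 of 57 cases (adjusted p = 0.000828, but adjusted p = 0.994 with an estimated correlation), with Hist2h3b at 0.36 and Hist1h4b at 0.22. For these lists fry called 0, and the count adjusted over the list alone was 0. Ribosomal protein genes had an adjusted p of 0.0830 without SP replicate 3, oxidative phosphorylation genes 0.0544 without ABX replicate 2, and histones 0.516 without ABX replicate 3, 0.0676 without SPF replicate 1, 0.136 without SP replicate 1 and 0.449 without SP replicate 2. The count of lists was 6 without SPF replicate 3 or ABX replicate 3, 7 without SPF replicate 2 or ABX replicate 1, and 8 without SP replicate 3. Median, mean and test differed in sign for monoamine neurons, pericytes, red blood cells, immediate early, cholesterol, interferon and microbial metabolite genes, none of them called.

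Whether SP moved genes back toward SPF was asked of the 200 genes with the smallest p in ABX against SPF, since fewer than 10 were called. Of these, 94% had the opposite sign in SP against ABX. Simulated data with no effect gave 92.7% (87.5% to 96.5%), because both contrasts contain the ABX libraries. Across genes, which are not independent replicates, the correlation of the 2 log2 fold changes was -0.519, and simulations gave -0.510 (-0.604 to -0.400). The covariance was -0.0409, and simulations gave -0.0555 (-0.0782 to -0.0452). The share and the correlation lay within the simulated range, and the covariance lay outside it, nearer to 0. Simulated genes varied independently, so these ranges may be too narrow for real genes that vary together. Without each library in turn the correlation ran from -0.678 to -0.343 and the covariance from -0.100 to -0.0423. DESeq2 gave a correlation of -0.520 and a covariance of -0.285. It ran without the edgeR filter (20172 genes tested), so its covariance is not over the same genes. These settings were not simulated, so the place of the covariance is known for the full data alone. The 3 ABX libraries cannot be divided into parts with at least 2 each.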

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

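The tests of Lars2, of the antibiotic group, of batch labels, of the group share of head tissue genes, and of tissue and group for SP replicate 3 were chosen after the result was seen. Among reads outside the main measurement, 2 classes stood above the control level, each in 1 group. Reads in no feature, in more than 1 gene and aligned to more than 1 place were checked in both ABX and SP. A class was flagged where each library of a group lay above every SPF library. That order can arise by chance in groups of 3 and was not tested. Reads aligned to more than 1 place made up 24.2%, 19.0% and 15.9% of listed reads in ABX replicates 1, 2 and 3, against 11.6% to 14.5% in SPF and 13.2% to 13.8% in SP. Reads in more than 1 gene made up 0.417%, 0.428% and 0.429% in SP replicates 1, 2 and 3, against 0.392% to 0.415% in SPF. In ABX that class was lower than in SPF, at 0.312%, 0.344% and 0.387%.

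Rn45s, the ribosomal RNA precursor, was higher in the ABX libraries than in the other 6 by 2.34 on the log2 scale (exact two-sided permutation p = 0.0119, the smallest that 84 splits can give). Lars2, whose locus holds a ribosomal RNA repeat, followed Rn45s over the 9 libraries with r = 0.903 (exact permutation p = 0.000628, adjusted 0.000628 over 2 relations; rho = 0.983, p = 4.96e-05; r = 0.938 without the 2 farthest libraries). Both can count reads of ribosomal RNA, so any cause that raises it would give such a correlation. Residual ribosomal RNA therefore stays open, and the correlation cannot tell it apart from the group. The permutation p restates that the 3 ABX libraries are the highest, for which the gene was picked, so the antibiotic group stays open and untested. A library batch that follows the group cannot be told apart from it, because 0 samples have labels naming a batch, date, lane or run.

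Genes of cartilage and muscle differed between libraries of 1 group, and a candidate explanation is tissue from outside the brain in the dissected samples. Listed cartilage genes and further cartilage genes (3 tested of 7, written before the result was seen) followed each other over the 9 libraries with r = 0.973 (exact permutation p = 6.06e-05, adjusted 0.000121 over 2 relations; rho = 0.900, p = 0.00203; r = 0.993 without the 2 farthest libraries). Groups held 5.13% of the sum of squares of the list mean, but the pattern was picked because libraries of 1 group differ, so the microbiome group stays untested. Any cause that moves cartilage genes together would give such a correlation, so it does not show that tissue was brought in.

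SP replicate 3 was high for cell cycle (0.46) and histone genes (0.43) and low for synapse genes (-0.38), in mean log2 deviation. The higher cell cycle value of the other 2 SP libraries was -0.108, but the pattern was picked because this library stood apart from them, so the spore-former group stays untested. For cartilage, muscle and skin tissue, the libraries with more expression of that list were SPF replicate 2, ABX replicate 1 and SP replicate 2. Their cell cycle values were -0.292, -0.118 and -0.108, so in them more of that expression did not go with high cell cycle values. This library was picked for the highest cell cycle value, so no other could reach it, and the comparison gives no verdict on that tissue. Other outside tissue also stays open. Olfactory (2.79) and liver and yolk sac genes (2.49), with 2 genes each and chosen after their values were seen, were highest in this library. ABX replicate 1 was nearly as high (2.49 and 2.16) with a cell cycle value of -0.118. SPF replicate 3 had 2.09 for olfactory genes with a cell cycle value of 0.0920. An earlier stage of development may be involved but stays open: genes of early minus late stages stood at 0.105 in this library, above the median of the other 8 (-0.0345) and below their highest (0.355).

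Other splits of the libraries were counted for genes and for lists. Each comparison of 3 with 3 has 10 splits, too few for a share under 0.05. For genes the real counts were 0, 0 and 0 in ABX against SPF, SP against ABX and SP against SPF, and the highest other counts 57, 1 and 0. A real count of 0 is met by 10 of 10 splits whatever the data, so this comparison tests nothing. For lists the real counts were 7, 2 and 7 and the highest others 10, 13 and 13, with 5, 10 and 8 of 10 splits as large. In ABX against SPF, 20 simulated sets with no effect called a mean of 0.1 lists and at most 2. Simulated genes varied independently, so these sets do not show how many lists shared variation between libraries would call. In SP against SPF, where every same-numbered correlation was above 0.1, the other 3 splits that part 3 pairs called 1 to 13 lists. The 6 that part 1 pair called 6 to 11, and both kinds of split called 0 genes. For ABX against SPF and SP, the real count of 0 genes (highest other 163) is likewise met by 100 of 100 splits and tests nothing. These 100 were the real grouping and groupings into 3 groups of 3 drawn at random. A drawn grouping also kept the 3 ABX libraries together and exchanged SPF and SP libraries. For lists 91 of 100 splits gave at least the real 3 (highest other 13), so chance is not excluded for the lists. The splits with 57 and 163 genes point to a structure of the samples. The first parts SPF replicates 1 and 3 and ABX replicate 3 from SPF replicate 2 and ABX replicates 1 and 2. Head tissue genes were at -1.44 to -1.06 and at -0.09 to 2.16 in these parts. Inner ear genes (2 tested) were at -1.73 to -1.22 and 2.54 to 2.82, and cranial sensory ganglia genes (6 tested) at -2.47 to -2.03 and up to 1.87. The inner ear and ganglia genes were chosen after their values were seen, and the splits were picked for their counts of genes. Their values therefore describe the split and test no cause. The second parts SPF replicate 2, ABX replicate 1 and SP replicate 2 from the other 6, following the head tissue genes.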

How the results depend on the processing

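Covariates for head tissue and Rn45s, alone or with the Y-linked covariate, and removal of Rn45s and Lars2 were chosen after seeing the data. The count of genes stayed at 0 in each contrast under other size factors, filters, limma-voom, the Y-linked covariate and a threshold of 0.1. It also stayed at 0 in each with the head tissue covariates and the Rn45s covariate alone. Fits of 2 groups gave 0 in ABX against SPF, SP against ABX and SP against SPF, the contrasts they cover. DESeq2 gave 1 in ABX against SPF and SP (Rn45s, log2 fold change 2.41). The Y-linked and Rn45s covariates together gave 1 in ABX against SPF, 1 in SP against ABX and 1 in ABX against SPF and SP, the trophoblast gene Tpbpa. The cause was not tested. Without each library in turn, genes ranged from 0 to 0 in all 4 contrasts. Lists called ranged from 3 to 8 in ABX against SPF, 1 to 6 in SP against ABX, 1 to 11 in SP against SPF and 2 to 8 in ABX against SPF and SP. Of the 19 list calls, 1 held without each library in turn, with camera's preset correlation throughout. Ntng1 ranged from -0.24 to 0.01 in ABX against SPF, from -0.21 to 0.04 in SP against ABX and from -0.30 to -0.08 in SP against SPF. It turned positive in ABX against SPF without ABX replicate 3 (0.00557), and in SP against ABX without ABX replicate 1 (0.0445) and without SP replicate 3 (0.00810). The separation ratio ranged from 0.178 to 0.303, and the share of opposite sign from 86.5% to 99%, with 100% for the 41 genes at an unadjusted p under 0.01.

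Lists called fell to 0 in all 4 contrasts with an estimated correlation and to 0 with fry. The fry test asks whether the list itself moved in 1 direction and does not compare it with other genes. In SP against ABX they were 1 with the Y-linked covariate, 4 with the Y-linked and head tissue covariates and 6 with the Y-linked and Rn45s covariates. In ABX against SPF and SP they were 5 with the Rn45s covariate and 7 with the Y-linked covariate joined to either head tissue or Rn45s. Ntng1 in SP against ABX reversed to 0.23 with Rn45s and 0.31 with Y-linked genes and Rn45s. Each ABX library held more Rn45s than the other 6, so in contrasts with ABX this covariate is confounded with the group. With the Rn45s covariate, reversed values in ABX against SPF were Mylpf -1.26, Actc1 -3.23 and Irs4 -0.25. In SP against ABX they were Aurka -0.0476, Ccnb1 -0.11 and Dlx5 0.0664, and in ABX against SPF and SP Irs4 -0.10 and Cycs 0.10. With Y-linked genes and Rn45s, ABX against SPF gave Ndufs4 0.00960, Actc1 -0.39 and Irs4 -0.52. SP against ABX gave Thoc7 -0.00291, Irs4 0.33, Cycs -0.0199, Ccnb2 -0.0679, Aurka -0.20 and Ccnb1 -0.48, and ABX against SPF and SP gave Irs4 -0.43 and Cycs 0.16. Actc1 in ABX against SPF was -2.47 without ABX replicate 1 and ranged up to 4.06 without SPF replicate 2. The cause was not tested.

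With the replicate number as a block, genes called were 0 in ABX against SPF, 0 in SP against ABX, 0 in SP against SPF and 0 in ABX against SPF and SP (387, 296, 324 and 330 at an unadjusted p under 0.05). Lists called were 9, 2, 8 and 3 and Ntng1 -0.10, -0.10 and -0.21, and the block changed no other reported count by over 1.5 times. Low-count genes, such as Creb3l1 at 0.473 CPM in SPF, rest on few reads, and how far depth limits them was not tested.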

Other observations

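The genes in this part were chosen after their values were seen, and the values are counts per library for replicates 1, 2 and 3. The cartilage gene Acan had 1, 811 and 5 counts in SPF, 360, 232 and 1 in ABX and 1, 210 and 44 in SP. Myh3, an embryonic muscle myosin, had 4, 39 and 6 in SPF, 252, 12 and 2 in ABX and 23, 151 and 137 in SP. The inner ear gene Oc90 had 1, 195 and 2 in SPF, 62, 120 and 2 in ABX and 3, 1 and 1 in SP. Prph, an intermediate filament of peripheral neurons, had 25, 593 and 21 in SPF, 327, 375 and 33 in ABX and 363, 208 and 135 in SP. Acsm4, of the olfactory epithelium, had 1, 3 and 32 in SPF, 27, 1 and 2 in ABX and 2, 3 and 51 in SP. The skin keratin Krt14 had 92 counts in SP replicate 2 and 14 in ABX replicate 1, with 0 or 1 in each of the others. The liver and yolk sac gene Afp had 65, 2 and 8 in SPF, 113, 1 and 46 in ABX and 7, 13 and 164 in SP.

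The trophoblast gene Tpbpa had 63, 0 and 5 counts in SPF, 0, 2 and 93 in ABX and 0, 2 and 10 in SP. The placental genes Tpbpb and Prl3b1 were likewise highest in SPF replicate 1 (48 and 46) and ABX replicate 3 (39 and 47). Hoxa5, expressed in the posterior hindbrain and spinal cord, had 161 counts in SPF replicate 2, 2 in SP replicate 2 and 0 in each of the other 7 libraries.

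At an unadjusted p under 0.05 the real grouping gave fewer genes than most other splits of the same libraries. In ABX against SPF it gave 356, against a median of 412 over the other splits, and in SP against ABX 294 against 613. It gave 280 against 800 in SP against SPF, and 334 against 578 in ABX against SPF and SP, where 91 of the other splits lay above it. Simulated libraries with no effect, in which genes varied independently, gave a mean of 675 in ABX against SPF (616 to 730). Single libraries moved the real counts, and neither the other splits nor the simulations were repeated without them. Without SPF replicate 3 the counts were 815 in ABX against SPF, 505 in SP against SPF and 566 in ABX against SPF and SP. Without SP replicate 3 they were 556 in ABX against SPF and 543 in ABX against SPF and SP, and without SP replicate 1 they were 443 in SP against ABX and 456 in SP against SPF. With Y-linked and Rn45s covariates ABX against SPF gave 696.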
